A study of Mus musculus with 16 samples.

How the data were processed

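Hippocampal RNA of 8-month-old female mice was profiled by bulk RNA sequencing in 16 libraries, 4 in each of 4 groups. The groups cross 2 genotypes: the PS19 tau transgene, present or absent, and the p16 gene, intact or knocked out. They are called WT, p16KO, PS19 and PS19_p16KO here, and each library is named by its group and the replicate number of its title. Per the labels' protocols, total RNA was extracted with column kits, and library preparation and the first processing steps were done by a commercial provider. Nothing in the labels says in words that the 4 samples of a group came from separate animals, so p-values measure the spread between these samples.

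The authors deposited one table of raw counts per gene, with 49671 gene rows and 92 rows of ERCC spike-in transcripts. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b, featureCounts, Subread 1.5.2 and DESeq2 were used with the genome build GRCm38. The notes give neither the role nor the order of these tools. The annotation release and the strand setting are not given in the sources used here, so reads of overlapping and antisense genes may be shared between them, and near-identical copies are uncertain. Gene symbols and coordinates were taken by Ensembl identifier from a GENCODE annotation of the same build name, and 49412 of the gene rows had a symbol. All coordinates are 1-based positions in GRCm38.

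The ERCC rows were left out of library sizes and tests. They held between 0.574% and 1.06% of the counts of a library. Gene counts per library ran from 18485552 to 22311322, and levels are given as CPM, counts scaled to a common library size after TMM scaling. Counts differed between every pair of replicates by more than sampling noise, with a chi-square per degree of freedom of 4.82 to 26.3, so no library was treated as a repeat of another.

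Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 16372, and libraries were scaled by TMM. All 16 libraries entered a single quasi-likelihood fit with a robust dispersion and one mean per group. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Log2 fold changes are given ± a standard error taken from the quasi-likelihood F statistic. There were 7 comparisons: PS19 against WT, p16KO against WT, PS19_p16KO against PS19, PS19_p16KO against p16KO, the interaction of the genotypes, and the effect of each genotype averaged over the other.

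The groups, the tests, 38 gene lists, the rule for named genes and all alternatives except 3 were fixed before the data were examined. Lists were tested with camera from limma 3.58.1, with a preset correlation between genes of 0.01, and p-values were adjusted over the lists of a comparison. Camera with an estimated correlation, which is much stricter here, and fry were the alternatives, and list calls below are described as changes only with that limit beside them. A score per library was the mean over a list of z-scaled log2 CPM (prior count 2), tested with exact permutation tests over 70 assignments, for which the smallest two-sided p is 0.0286.

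Genes named in the text follow a fixed rule. Cdkn2a, Mapt and Prnp are always given. For each comparison the 10 largest rises and 10 largest falls are taken among called genes with a mean log2 CPM above 0 and, in pairwise comparisons, no overlap between the libraries of the groups, leaving out predicted and unnamed models. Up to 4 members with the smallest adjusted p are taken from each list described, and up to 10 genes from the interaction. Any other gene named was chosen after its values were seen, and this holds for Lamr1-ps1, 4930590L14Rik, Gm6166, Cd22, Ly9, H2-Ob, Slamf9, Ttr, Gbp2b, Tyrobp, Pdcd1, Nnt in single groups, Xist, Ddx3y, 1110002E22Rik and the genes described by position. Some genes that the rule names are not reported here.

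The alternatives were RLE scaling, DESeq2 1.42.0, limma-voom with sample quality weights, no filter, a filter of CPM above 1 in 4 libraries, the replicate number as a block, the first digit of the library-name suffix as a batch term, 1 surrogate variable from sva 3.50.0, only the compared groups in the fit, no robust dispersion, a minimum fold of 1.2, and leaving out each library in turn. The other 3 were chosen after seeing the data: leaving out the 3 libraries with the highest choroid plexus scores, the choroid plexus score as a covariate, and the leading number of the library name as a covariate. A fit without the PS19 libraries with the highest microglial scores was also run and is not used, because it picks samples by the outcome that is compared.

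The procedure was tested on simulated counts drawn from the real means, library sizes and dispersions, each gene independently of the others. In them 200 genes with a mean above 1 CPM were changed, and 4 further sets of genes were changed 1.3-fold. The shares below therefore do not cover genes of lower level. In the simulated comparison of PS19 with WT, over 16227 genes, edgeR called 66% of the 1.5-fold changes and 94% of the 2-fold changes. In the simulated interaction those shares were 46% and 76%. Of its calls in PS19 against WT, 4.57% were on unchanged genes.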

Results

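The hippocampus of 8-month-old female mice was sequenced as bulk RNA in 4 groups of 4 libraries. PS19 mice carry a human tau transgene with a disease mutation and are used as a model of tauopathy. The protein p16, encoded together with another product by Cdkn2a, is an inhibitor of the cell cycle and a marker of senescent cells. The design asks what the transgene does to hippocampal expression, what loss of p16 does, and whether the transgene effect differs when p16 is missing. Libraries held between 18485552 and 22311322 gene counts, and 16372 genes were tested.

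The targeted gene was examined first. Cdkn2a (chromosome 4, 89274471 to 89294653) was close to the detection limit in every group, with 8 counts in all over the 4 WT libraries, 18 over the PS19 libraries, 3 over the p16KO libraries and 2 over the PS19_p16KO libraries. Its mean level was 0.236 CPM ± 0.157 (SD, n = 4) in PS19 and 0.0252 CPM ± 0.0292 in PS19_p16KO (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 libraries can give, adjusted p = 0.114 over 20 tests of this kind). Over all 8 knockout libraries against the other 8 the exact permutation p was 0.00326 (adjusted p = 0.0652). The direction goes with the labels, but whether the counts cover the deleted part is not given in the sources used here, and the gene was too low to enter the tested set. Prnp, the prion protein gene, whose mouse promoter drives the PS19 transgene, had 1020 CPM ± 36 in WT, 1070 CPM ± 7.24 in p16KO, 1770 CPM ± 224 in PS19 and 1870 CPM ± 60.8 in PS19_p16KO. Whether these counts include reads of the transgene itself was not tested. Mouse Mapt lay between 507 and 569 CPM in the group means and was called in no comparison. Xist lay between 106 and 250 CPM and the Y-linked gene Ddx3y reached at most 1.53 CPM over all libraries.

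**Figure D1:**
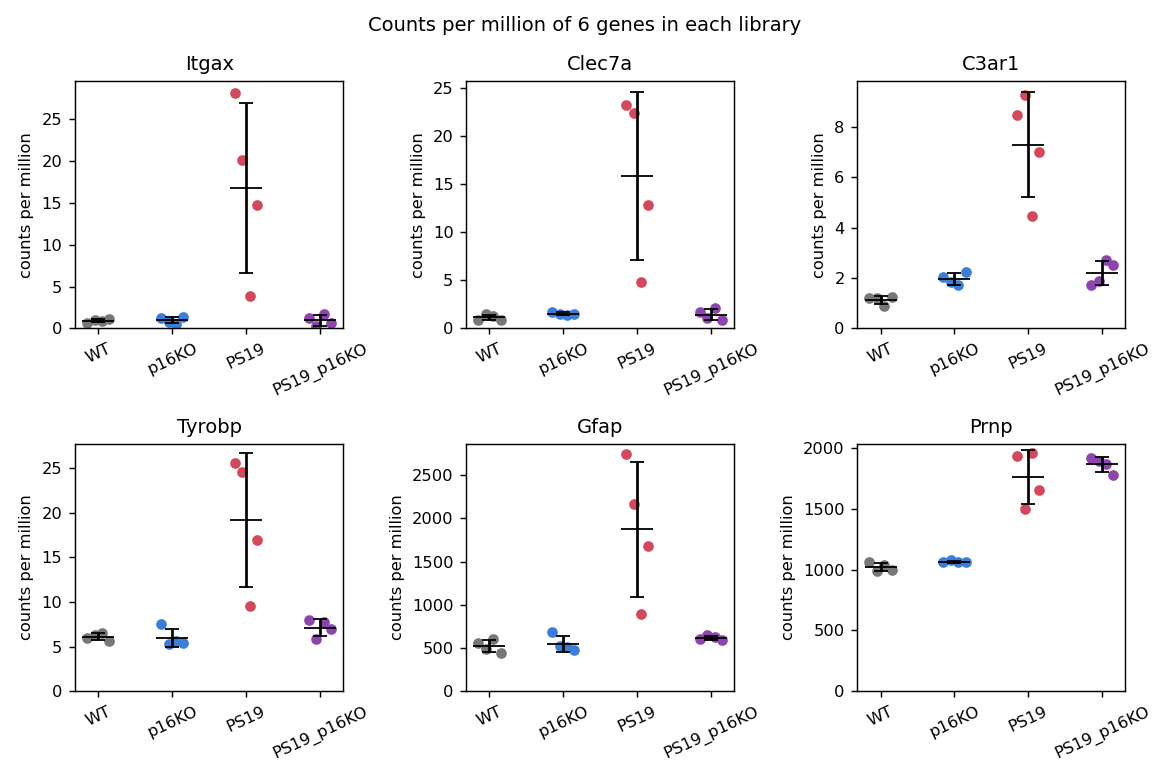
CPM (counts scaled by library size, on a linear axis) of 6 genes, with 1 point per library, the group mean as a bar and the SD as an error bar (n = 4). The means of Itgax, Clec7a, C3ar1, Tyrobp and Gfap are highest in PS19, where single libraries spread widely, while Prnp is high in both groups that carry the transgene.

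To determine what the transgene changed when p16 was intact, PS19 was compared with WT. Among called genes with a mean log2 CPM above 0 and no overlap between the libraries of the groups, predicted models left out, the largest rises were in genes of activated microglia. Itgax, an integrin of activated microglia, rose 18.6-fold (log2 4.22 ± 0.58, adjusted p = 0.00221) and Clec7a, a receptor for fungal glucans that marks the same state, 13.8-fold (log2 3.79 ± 0.43, adjusted p = 0.000393). The chemokine genes Ccl6 and Ccl9 rose 8.38-fold and 8.2-fold, Cd52 rose 7.01-fold, and C3ar1, the receptor for the complement fragment C3a, rose 6.39-fold (adjusted p = 1.24e-06). Lag3, Cd74, Siglecf and AU020206, at 4.12-fold to 5.79-fold, completed the 10 largest rises within these limits. Outside them 4930590L14Rik, Lamr1-ps1, Gbp2b and Cst7 rose more than Itgax (log2 6.9, 6.03, 5.56 and 5.08). In all, 264 genes passed edgeR's quasi-likelihood test, 255 higher and 9 lower. In 232 of these called genes the libraries of the groups did not overlap, which calling them on the same libraries favours. Over all tested genes 5.04% did not overlap, where chance gives 2.86%. Among the falls, Crybb1, a crystallin gene also expressed in microglia, lay at 0.407 of its WT level, while Fam198b, Prokr2, Msmo1, Fdps, Npy1r, Slc26a4 and Sh3bp4 lay between 0.638 and 0.841.

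By list, the microglial, complement, lysosomal and reactive astrocyte lists were called higher in PS19. Of 24 genes of disease-associated microglia, 14 were higher and all 24 had a positive fold change, with a median log2 fold change of 0.99 (18 higher when adjusted over the list alone). Cst7, a cystatin of lysosomes, rose by 5.08 on the log2 scale from 0.189 CPM ± 0.094 in WT to 6.59 CPM ± 4.13 in PS19. Of 14 general markers of microglia and macrophages 12 were higher, among them Fcgr3, Laptm5, Ly86 and Irf8 at log2 1.12 to 1.67, and of 14 homeostatic microglial genes 6 were higher, including Csf1r (1.82-fold), Cx3cr1 (1.57-fold) and Fcrls (2.29-fold). Adjusted over the list alone those counts were 14 and 9. Complement genes rose in 6 of 15, with C4b at log2 1.90 and C1qb at 1.59, and lysosomal genes in 13 of 22, with Cd68 at 1.56 and Hexa at 0.61 (6 and 19 adjusted over the list alone). Of 16 genes of reactive astrocytes 4 were higher, namely Osmr (log2 1.92), Gfap (1.84), Ggta1 (2.47-fold) and Aspg (log2 1.56), and 10 when adjusted over the list alone. Gfap, the astrocyte filament protein, stood at 523 CPM ± 69.8 in WT and 1870 CPM ± 784 in PS19, where single libraries ran from 897 to 2750 CPM. These 6 lists were called by camera and also with an estimated correlation, with adjusted p = 0.0085 for the disease-associated and the general microglial lists, 0.0219 for the homeostatic list and complement, 0.0134 for lysosome and 0.0316 for reactive astrocytes.

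Other lists were called by camera but not with an estimated correlation, and endothelial identity and barrier transport were not called by camera either. Fry called 9 of the 38 lists in this comparison. Interferon response genes had a median log2 fold change of 0.86 and 27 of 27 positive values, but only Ifit3b (1.28) and Cxcl10 (1.62) passed over all genes, against 16 adjusted over the list alone (adjusted p = 0.103 with an estimated correlation). In antigen presentation Psmb8, Cd74 and B2m were higher among 15, and 7 adjusted over the list alone (adjusted p = 0.0501 with an estimated correlation). Of 31 genes of senescence and its secreted factors 4 were higher, Axl, Cxcl16, Plau and Tgfb1, and adjusted over the list alone 13 were higher and 1 lower (adjusted p = 0.0501 with an estimated correlation). These 4 encode a phagocytic receptor, a chemokine, urokinase and a growth factor. Cholesterol synthesis had 0 of 20 positive values and a median of -0.24, and Fdps and Msmo1 were lower, 5 adjusted over the list alone (adjusted p = 0.121 with an estimated correlation). Oligodendrocyte and myelin genes had 16 of 16 positive values and a median of 0.32, and identity genes of astrocytes 14 of 14 and a median of 0.20, with 0 calls over all genes and 8 adjusted over the list alone in each (adjusted p = 0.135 with an estimated correlation in both). Of the 20 endothelial identity genes 0 were called, with a median of -0.08 (camera adjusted p = 0.0531). Of 20 genes of barrier transport and junctions, Slc7a5, a transporter of large neutral amino acids, was higher (log2 0.40, adjusted p = 0.0419), 2 adjusted over the list alone, and the list's median was 0.05 (camera adjusted p = 0.306).

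The PS19 libraries differed in these lists. The score of disease-associated microglia was 0.05 in PS19 library 3, against 1.98, 1.70 and 1.18 in libraries 1, 2 and 4, and library 3 was also the lowest of its group in the general microglial (0.199), lysosomal (0.081) and reactive astrocyte (-0.026) scores. Per library, the exact permutation p of the disease-associated, general microglial, homeostatic and lysosomal scores was 0.0286, that of reactive astrocytes 0.0571 and that of complement 0.0857 (adjusted p = 0.155 for the first 4, 0.181 and 0.233). The number of calls was 124 without PS19 library 1, 131 without PS19 library 2, 438 without PS19 library 3, 143 without WT library 2 and 166 without WT library 4, and 70 when only PS19 and WT were fitted.

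**Figure D2:**
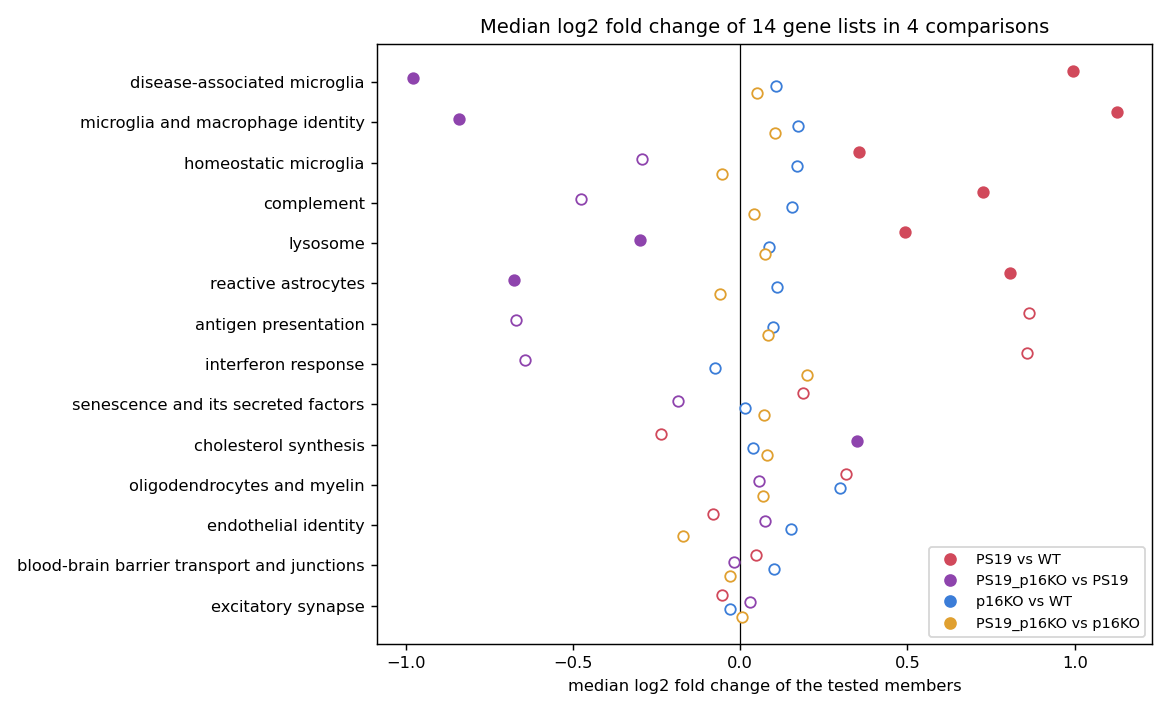
Median log2 fold change of the tested members of 14 gene lists in 4 comparisons. Filled points passed camera with an estimated correlation, and open points did not, and the microglial lists lie to the right in PS19 against WT, with medians up to 1.13, and to the left in PS19_p16KO against PS19.

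To ask what loss of p16 did in mice with the transgene, PS19_p16KO was compared with PS19. Within the same limits on level, overlap and predicted models, microglial genes led the falls. Itgax was at 0.0581 of its PS19 level (log2 -4.11 ± 0.58, adjusted p = 0.00693) and Clec7a at 0.0909 (log2 -3.46 ± 0.42, adjusted p = 0.00267). Siglecf, Ccl6, Lag3, Serpinf2, Cd84, Ccl9, Endou and Slc11a1 followed, at 0.216 to 0.296 of the PS19 level. Outside the limits Gm6166 and Pdcd1 fell more than Itgax (log2 -4.55 and -4.13), and Cst7, Cd22, Ly9, H2-Ob and Slamf9 more than Siglecf. In edgeR's test 135 genes changed, 127 lower and 8 higher. In 118 of these called genes the libraries did not overlap, which calling them on the same libraries favours. Over all tested genes 4.09% did not overlap. Of the 8 higher genes, Fdps, Insig1 and Msmo1 belong to cholesterol synthesis and its control, at log2 0.46, 0.50 and 0.42, and Arhgef19, a guanine nucleotide exchange factor gene, had log2 0.85 ± 0.15. Slc30a3, Scg5 and Gipc1 rose by log2 0.33, 0.30 and 0.23.

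By list, 10 of 24 disease-associated microglial genes were lower, 19 adjusted over the list alone, with 0 positive fold changes and a median of -0.98. Cst7 fell by 3.97 on the log2 scale and Cd68 by 1.43. Of the general microglial markers 7 of 14 were lower, with Ptprc at 0.406 of its PS19 level and Ly86 at log2 -1.50, and 13 adjusted over the list alone. Reactive astrocyte genes were lower in 4 of 16, Osmr, Gfap, Ggta1 and Aspg, and 9 adjusted over the list alone, and Gfap stood at 619 CPM ± 24.3 in PS19_p16KO. Of 22 lysosomal genes Cd68, Grn, Ctss and Hexa were lower, and 14 adjusted over the list alone. Cholesterol synthesis genes were higher in 3 of 20, and all 20 passed when adjusted over the list alone, with a median of 0.35. These 5 lists kept their call with an estimated correlation, with adjusted p = 0.0229, 0.0269, 0.0399, 0.0433 and 0.0269 in that order. The remaining lists did not keep it. Complement had 6 of 15 lower, C3ar1, Itgb2, C4b and C1qb first among them, and adjusted over the list alone 7 lower and 2 higher (adjusted p = 0.05 with an estimated correlation, just above the threshold). Astrocyte identity had 1 of 14 genes lower, Slc1a2, 8 adjusted over the list alone, a median of -0.18 and 1 positive value (camera adjusted p = 1.46e-09, adjusted p = 0.0979 with an estimated correlation). Homeostatic microglial genes had 2 of 14 lower, Fcrls and Csf1r, and adjusted over the list alone 8 lower and 1 higher (adjusted p = 0.0974 with an estimated correlation). The senescence list had 4 of 31 lower, among them Axl, Ccl3 and Plau, and adjusted over the list alone 13 lower and 1 higher (adjusted p = 0.0768 with an estimated correlation). In the interferon list Cxcl10 was lower, and 7 adjusted over the list alone (adjusted p = 0.0979 with an estimated correlation). Dentate gyrus genes had 0 of 12 called over all genes, 1 higher adjusted over the list alone, 11 positive values and a median of 0.17 (camera adjusted p = 1.8e-05, adjusted p = 0.0979 with an estimated correlation), and the scores of that list were lowest in PS19 libraries 1 and 2 (-1.109 and -1.07). Endothelial identity had 0 calls among 20 genes and a median of 0.08 (camera adjusted p = 0.0483, adjusted p = 0.692 with an estimated correlation).

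Per library, the exact permutation p was 0.0286 for the disease-associated, general microglial and cholesterol synthesis scores and 0.0571 for reactive astrocytes and lysosome (adjusted p = 0.31 in each). The number of calls moved with the libraries and the model. It was 46, 29 and 347 without PS19 libraries 1, 2 and 3, and 49, 36 and 46 without PS19_p16KO libraries 1, 2 and 4. It was 62 without the 3 libraries rich in choroid plexus RNA, 8 when only these 2 groups were fitted, 37 with a minimum fold of 1.2, 87 with a batch term for the library-name suffix, 269 by DESeq2 and 77 by limma-voom.

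Of the 255 genes higher in PS19 than in WT, 100 were among the 127 lower in PS19_p16KO than in PS19, against 1.98 for independent lists. The comparisons share the PS19 libraries, and simulated groups without any effect, where the overlap was 0, cannot show what sharing adds among called genes. The PS19 libraries were split into pairs, 2 compared with WT and the other 2 with PS19_p16KO. Over the 6 such splits between 4 and 40 genes were called in both, and between 81.5% and 96.4% of the genes called higher in the first pair had a negative fold change in the second. Across all tested genes, differences of group means of log2 CPM correlated at r = -0.633, against -0.503 for simulated unchanged groups, with a covariance of -0.0456 against -0.0243. Spearman's rho was -0.45, against -0.455 in those simulated groups, so the ranks showed no opposition beyond that of the shared libraries. With the libraries split, r lay between -0.333 and -0.195, rho between -0.149 and -0.0176 and the covariance between -0.0292 and -0.0191. Genes are not independent replicates, so no p is given.

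To see whether p16 mattered without the transgene, p16KO was compared with WT. The count in edgeR's test was 0 genes, where 653 had an unadjusted p under 0.05, DESeq2 called 18 and limma-voom 11. The count was 2 without WT library 1 and 1 without WT library 4, p16KO library 1 or p16KO library 3. The fitted log2 fold changes were 0.07 ± 0.06 for Mapt and 0.06 ± 0.07 for Prnp. Camera called 17 lists, all higher. Oligodendrocyte and myelin genes had a median of 0.30, 16 of 16 positive values and 4 calls adjusted over the list alone, with Opalin at log2 0.39 and Fa2h at 0.46. The pericyte and smooth muscle list had a median of 0.27 and 2 calls adjusted over the list alone, fibroblasts and meninges a median of 0.36 with 14 of 14 positive values (camera adjusted p = 0.000912, adjusted p = 0.723 with an estimated correlation), and endothelial identity a median of 0.15 with 17 of 20 positive values. Microglial lists were among the 17, the homeostatic list with a median of 0.17 and 14 of 14 positive values (camera adjusted p = 1.51e-06), the general markers with 0.17 (0.011) and the disease-associated list with 0.11 (0.0221), and 0 of their genes were called. Per library the exact permutation p was 0.0571, 0.0286 and 0.0286 for these scores (adjusted p = 0.542 in each). With an estimated correlation 0 lists were called, with adjusted p = 0.295, 0.748 and 0.772 for these 3 microglial lists, adjusted p = 0.295 for oligodendrocytes and for pericytes and adjusted p = 0.35 for endothelial identity. The choroid plexus list had a median of 1.53 and turned direction in camera without p16KO library 4 (adjusted p = 0.331).

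The transgene effect without p16 was taken from PS19_p16KO against p16KO, which shares no library with PS19 against WT. In edgeR's test 3 genes passed, where 598 had an unadjusted p under 0.05, DESeq2 called 6 and limma-voom 4, and 5 passed without PS19_p16KO library 2. They were Prnp (log2 0.81 ± 0.07, adjusted p = 9.05e-07), Lamr1-ps1 and 4930590L14Rik, the last with 67 counts over the PS19_p16KO libraries and 2 over the p16KO libraries. All 3 were also higher in PS19 than in WT. Whether their counts come from the transgene construct and its surroundings or from a response to it was not tested. Of the 264 genes called in PS19 against WT, 164 had the same sign here (62.1%), but the median log2 fold change in the direction of the first comparison was 0.045 where it had been 0.92. Across those genes the fitted fold changes had Pearson's r of 0.507 and Spearman's rho of 0.282. With differences of group means of log2 CPM, r over the same genes was 0.366. The 3 genes called in both are among them, with median log2 fold changes of 4.814 here and 6.025 in PS19 against WT. The correlation without those 3 was not computed. Over all 16372 tested genes the same sign was found in 56.5%, with r of 0.14 and rho of 0.144. Itgax was at 0.999 CPM ± 0.398 in p16KO and 0.965 CPM ± 0.645 in PS19_p16KO, and Clec7a at 1.53 CPM ± 0.149 and 1.43 CPM ± 0.57. Camera called 15 lists, 9 of them lower, and 0 with an estimated correlation. The pericyte and smooth muscle list had a median of -0.38 and 0 of 15 positive values, with Mylk, Myh11 and Acta2 lower adjusted over the list alone (adjusted p = 0.281 with an estimated correlation). Fibroblasts and meninges had a median of -0.44 (camera adjusted p = 3.05e-05, adjusted p = 0.49 with an estimated correlation). Border macrophages had a median of -0.68 (camera adjusted p = 5.92e-05, adjusted p = 0.281 with an estimated correlation), and fry called 0 lists in this comparison. In the scores of these 3 lists p16KO library 2 was the highest of all libraries (1.644, 1.637 and 1.447). Endothelial identity had a median of -0.17 with Podxl lower adjusted over the list alone (adjusted p = 0.341 with an estimated correlation). The disease-associated microglial list had a median of 0.05 and a mean of -0.05, and the choroid plexus list a median of 0.53 although camera's direction was down (adjusted p = 0.919 and 0.637).

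Whether the transgene effect differed with p16 was tested by the interaction. A single gene passed edgeR's test, C3ar1 (ENSMUSG00000040552, chromosome 6, 122847138 to 122856161), with a log2 interaction of -2.52 ± 0.32 (adjusted p = 0.00248). It rose from 1.14 CPM ± 0.161 in WT to 7.29 CPM ± 2.1 in PS19, and lay at 1.96 CPM ± 0.218 in p16KO and 2.2 CPM ± 0.482 in PS19_p16KO. Limma-voom called 0 genes, where C3ar1 had an adjusted p of 0.0545, and 890 genes had an unadjusted p under 0.05 in edgeR. DESeq2 called 84, of which 83 were lower. The count was 3 without WT library 1 or PS19 library 4, 2 without WT library 4, p16KO library 4, PS19 library 1 or PS19_p16KO library 3, and 160 without PS19 library 3. Of the lists, 15 were called by camera and 6 also with an estimated correlation: disease-associated microglia (median -0.96, adjusted p = 0.0272), homeostatic microglia (-0.42, adjusted p = 0.0312), general microglial markers (-1.01, adjusted p = 0.0312), reactive astrocytes (-0.92, adjusted p = 0.039), complement (-0.89, adjusted p = 0.04) and lysosome (-0.37, adjusted p = 0.04). All 6 medians were negative, and 5 of the lists, all but reactive astrocytes, had also been called higher in p16KO than in WT by camera, which enters the interaction (medians of 0.11, 0.17 and 0.17 for the first 3, 0.16 for complement and 0.09 for lysosome). With an estimated correlation 0 lists were called in p16KO against WT. Adjusted over the list alone, 17, 8, 13, 9, 7 and 13 of their genes were lower in that order. Fry called the first 3 of these.

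Averaged over p16 genotypes, the transgene changed 64 genes in edgeR's test, 60 higher and 4 lower. Of the 60, 59 were also called higher in PS19 against WT, while PS19_p16KO against p16KO had 3 calls. Lamr1-ps1 (log2 5.69, adjusted p = 1.27e-10) and Prnp (log2 0.80 ± 0.05, adjusted p = 2.16e-09) had the smallest adjusted p. Among genes with a mean log2 CPM above 0, Clec7a, Ccl6, Lag3, Ccl9, Cd52, C3ar1, Siglecf, Mpeg1, C4b and Atf3 rose most, at log2 1.04 to 1.84. Arsj, 1110002E22Rik, Unc5c and Kif5a fell by 0.55, 0.65, 0.37 and 0.36 on the log2 scale. The disease-associated, general microglial and lysosomal lists were called with an estimated correlation (adjusted p = 0.0455 for each). The count was 34, 21, 33 and 33 without WT libraries 1 to 4, 39, 24, 15 and 24 without p16KO libraries 1 to 4, 25 and 206 without PS19 libraries 2 and 3, and 21, 34 and 41 without PS19_p16KO libraries 1, 3 and 4.

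Averaged over transgene genotypes, p16 knockout changed 37 genes, 16 higher and 21 lower. Of the 21, 15 were also called lower in PS19_p16KO against PS19, while p16KO against WT had 0 calls. Rsg1, Mfap2, Arhgef19, Pon2, Kcnj11, Fabp5, Nnt, Tusc1, Crocc and Cox7a2l rose most, at log2 0.36 to 0.99, and Padi2, Slc15a3, Myo1f, Tcp11l1, Eif2ak2, Cybrd1, Gpatch11, Paox and Heatr5b were among those that fell most, at log2 -0.24 to -0.86, among genes with a mean log2 CPM above 0 and without predicted models. The count was 12, 19 and 14 without WT libraries 2, 3 and 4, 14, 14 and 10 without p16KO libraries 1, 2 and 3, 12, 13, 119 and 21 without PS19 libraries 1 to 4, and 19 and 15 without PS19_p16KO libraries 1 and 2.

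The called genes of these averaged effects were not spread evenly over the genome. Of the 37 genes of the p16 effect 8 lay on chromosome 4 (21.6%), where Cdkn2a is also found, against 6.13% of tested genes. Klhl9 starts at 88718292, Tusc1 at 93334138 and Gm12655 at 94460931, and Padi2, Mfap2, Crocc, Rsg1 and Arhgef19 start between 140906344 and 141239499. On chromosome 17, 6 genes start between 73804134 and 83501918, Ehd3, Heatr5b, Gpatch11, Eif2ak2, Tmem178 and Cox7a2l. Of the genes called in the averaged transgene effect, Arsj, Alpk1, Tifa, 1110002E22Rik, 4930590L14Rik, Unc5c and Gbp2b start between 126363684 and 142594847 on chromosome 3. Gbp2b was also higher in p16KO (1.09 CPM) than in WT (0.0402 CPM), both without the transgene. Lamr1-ps1, a processed pseudogene, lies on chromosome 2 from 131904086 to 131904959, next to Prnp, which starts at 131909928, and it had 220 counts over the PS19 libraries, 254 over the PS19_p16KO libraries, 6 over the p16KO libraries and 3 over the WT libraries.

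**Figure D3:**
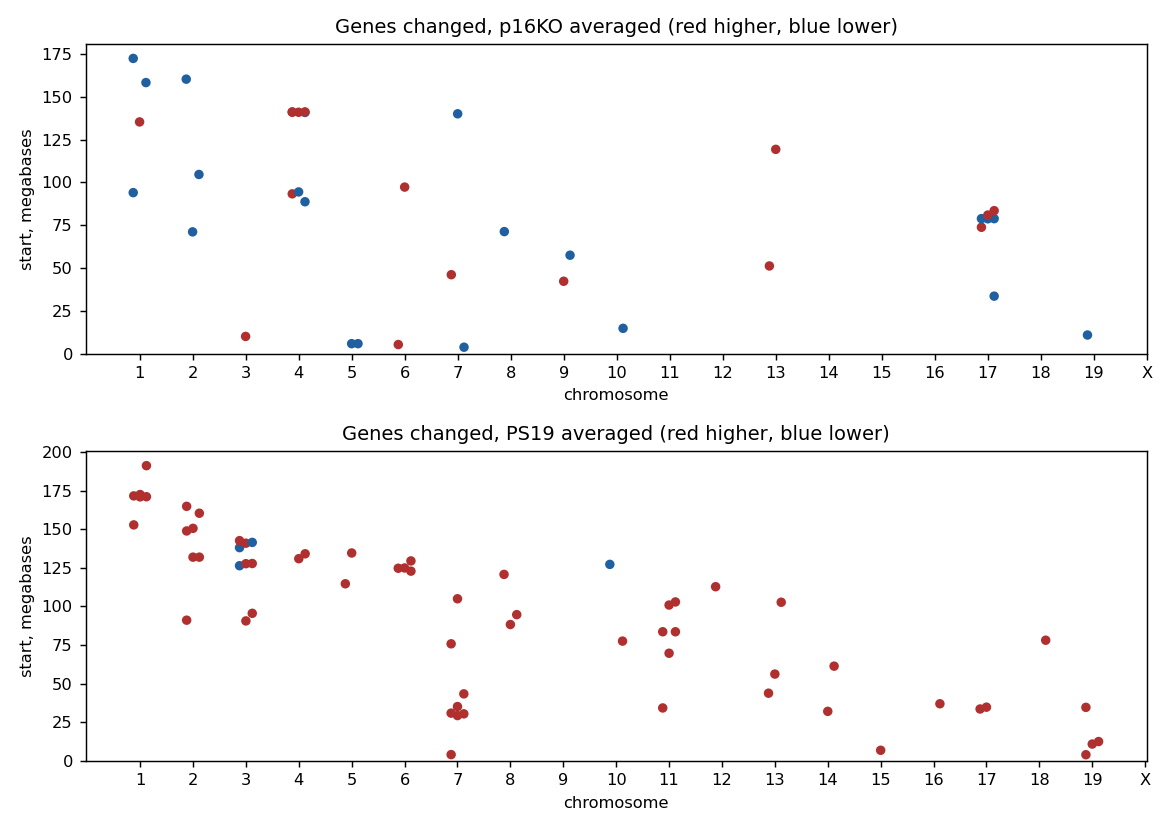
Chromosome and start position, in megabases of GRCm38, of the genes called in the averaged p16 knockout effect and the averaged PS19 effect, with 1 point per gene, red for higher and blue for lower. Groups of neighbouring genes stand on chromosomes 4 and 17 in the first and on chromosome 3 in the second.

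Libraries also differed in choroid plexus RNA within groups. Ttr, which the choroid plexus expresses at very high levels, was at 5120 CPM in PS19_p16KO library 3, 2970 CPM in p16KO library 4 and 713 CPM in WT library 1, and its mean in PS19 was 18.5 CPM ± 10.4. The choroid plexus list had a median of 3.48 in PS19_p16KO against PS19 (camera adjusted p = 0.000734, adjusted p = 0.692 with an estimated correlation) and of -1.60 in PS19 against WT (camera adjusted p = 0.0409, adjusted p = 0.676 with an estimated correlation). Its direction in camera turned without the 3 libraries in both (adjusted p = 0.113 and 0.345), without PS19_p16KO library 3 in the first (0.45) and without WT library 1 in the second (0.783).

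**Figure D4:**
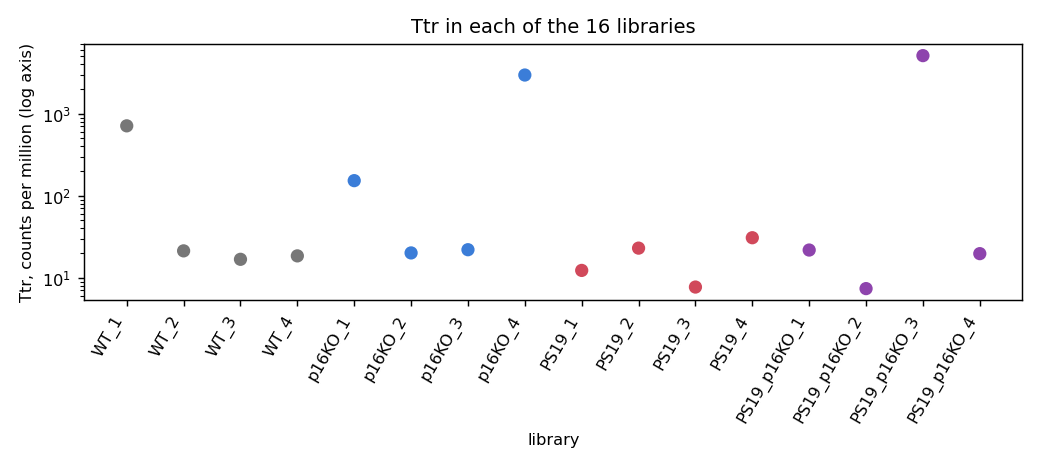
Ttr in CPM, on a log axis, in each of the 16 libraries, coloured by group. The value of PS19_p16KO library 3 is 5120 CPM, that of p16KO library 4 is 2970 CPM and that of WT library 1 is 713 CPM, each far above the rest of its group.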

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

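Among the tests in this part, those on Prnp, on the microglial and astrocyte lists and on the choroid plexus genes were chosen after the result was seen, as was the choice of the choroid-rich libraries to leave out.

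For C3ar1 the transgene effect was called different between p16 genotypes by edgeR, with a fitted interaction of -2.516 on the log2 scale (adjusted p = 0.0545 by limma-voom). It was called different by camera for 6 lists: disease-associated microglia with a median of -0.958, homeostatic microglia with -0.419, general microglial markers with -1.006, complement with -0.889, reactive astrocytes with -0.916 and lysosome with -0.367. Fry called only the first 3 of these lists.

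The pattern was that of glial genes higher in PS19 and lower in PS19_p16KO. Weaker expression of the transgene is argued against by Prnp, as far as its counts follow the transgene. Its log2 fold change between these groups was 0.08. Choroid plexus tissue is argued against by the median log2 fold change of the 127 falls, which moved by 0.01 without the choroid-rich libraries. In that fit, with fewer libraries, all 127 stayed lower, but only 48 were still called. Sequence carried along near Cdkn2a that acts only on genes beside it is argued against as the whole cause, because 11.8% of the falls lie on chromosome 4. Under 15% had been set as the bound, but this share is above the 6.13% of tested genes. Such sequence stays open for Klhl9 and Gm12655, the called genes that lie nearest to Cdkn2a. Carried sequence that acts on genes elsewhere need not raise this share, so the test cannot decide on it. The most crowded window, 10 of 135 called genes between 126024550 and 141239499 on that chromosome (reached by 84 of 10000 random sets), starts far from Cdkn2a and holds Csf3r, Laptm5, Ptafr, Fgr, Cd52, C1qa, C1qb and C1qc beside Padi2 and Arhgef19. A smaller number of microglia with no other change stays open for the microglial genes. The reactive astrocyte list fell too (median -0.675, adjusted p = 0.0399 with an estimated correlation, exact permutation p of its score per library 0.0571). That fall argues against fewer microglia alone for the astrocyte genes of the pattern. The argument is limited, because the bounds of that test were set after its values were known and the scores of single libraries overlapped. Among the microglial genes, the median log2 fold change of the disease-associated list lay at -0.68 from that of the homeostatic list, with an exact permutation p of 0.0571 per library. A change in glial state, or in the number of activated microglia, that depends on p16 may account for the pattern and remains an untested hypothesis.

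Other groupings of the libraries were fitted for each comparison. The real grouping gave the most calls in PS19 against WT (264, highest other 10, 1 of 35 splits as large), in PS19_p16KO against PS19 (135, highest other 105, 1 of 35), in PS19_p16KO against p16KO (3, highest other 1, 1 of 35), in the averaged PS19 effect (64, highest other 8, 1 of 100) and in the averaged p16 effect (37, highest other 1, 1 of 100). In each of these, groupings with as many calls made up a share under 0.05, not adjusted over the 7 comparisons. A share of 1 of 35 is also the smallest that those splits can give. The split with 105 calls exchanged PS19 library 3 for PS19_p16KO library 3. For the interaction 6 of 100 groupings gave at least the 1 real call, highest other 8, so chance cannot be excluded for that count. For p16KO against WT the real count was 0, which all 35 of 35 splits reach by construction (highest other 1), so the splits test nothing there.

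A sample stood far from its group in 19 of 200 groups of 4 tested, where chance gives about 5%. The gene count total was high in WT library 2 (22300000), p16KO library 1 (22200000) and PS19 library 2 (20600000). The ERCC share was 1.06% in PS19 library 1. The list score of blood cells was 1.94, that of basement membrane -0.497 and that of activity-regulated genes 1.47 in PS19_p16KO library 4. The score of astrocyte identity was -0.8 and that of thalamus and habenula -0.14 in p16KO library 4. The score of tau and transgene-related genes was -1.36 in PS19 library 2 and -0.119 in PS19_p16KO library 3. In p16KO, Clec7a was 1.75 CPM and Tyrobp 7.51 CPM in library 1, and in WT library 3 C3ar1 was 0.895 CPM. Prnp was flagged in p16KO library 2, at 1080 CPM against 1060 CPM in the other p16KO libraries. Those values were rounded before the test, so this flag may not hold.

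Choroid plexus genes stood apart through Ttr at 713 CPM in WT library 1, 2970 CPM in p16KO library 4 and 5120 CPM in PS19_p16KO library 3, and through a list score of 2.3 in the last. Of 16 choroid plexus genes tested, all 16 had p16KO library 4 and PS19_p16KO library 3 as their highest libraries.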

How the results depend on the processing

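The tests with the choroid-rich libraries left out, the choroid score or the leading number of the library name were chosen after seeing the data. Of 2886 refits of called named genes 2179 kept their call, 707 lost it and 0 changed direction. Of 2026 refits of called lists 1682 kept their call, 337 lost it and 7 turned direction. The 7 were the choroid plexus list in PS19 against WT (adjusted p = 0.345 without the choroid-rich libraries, 0.783 without WT library 1), in p16KO against WT (0.331 without p16KO library 4) and in PS19_p16KO against PS19 (0.113 without the choroid-rich libraries, 0.45 without PS19_p16KO library 3), fibroblasts and meninges in PS19 against WT (0.999 without WT library 3) and the respiratory chain in p16KO against WT (0.0459 without p16KO library 1), all from camera. Leaving out 1 library at a time gave adjusted p from 0.00193 to 0.783, 3.51e-06 to 0.331 and 4.89e-06 to 0.45 for choroid plexus in those comparisons, 8.22e-05 to 0.999 for fibroblasts and meninges and 1.18e-05 to 0.774 for the respiratory chain (0.774 without WT library 2). Over all comparisons camera called 122 lists, 20 with an estimated correlation and 23 by fry. Fits of only the compared groups use fewer samples, and for other changes the cause was not tested.

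Where an alternative moved a count of calls by over 1.5 times its values were as follows. PS19 against WT (264): 70 with only the compared groups fitted, 118 with a minimum fold of 1.2. PS19_p16KO against PS19 (135): 8 with only the compared groups, 37 with the minimum fold, 87 with the suffix batch term, 62 without the choroid-rich libraries, 77 by limma-voom, 269 by DESeq2. p16KO against WT (0): 4 without a filter, 4 with a surrogate variable, 4 with the choroid score, 2 with the leading number, 7 without the choroid-rich libraries, 9 with only the compared groups, 18 by DESeq2, 11 by limma-voom. PS19_p16KO against p16KO (3): 6 with a surrogate variable, the choroid score or DESeq2. Interaction (1): 6 with RLE, 20 without a filter, 13 with the suffix term, 2 without robust dispersion, 5 with a surrogate variable or the choroid score, 57 with the leading number, 84 by DESeq2, 0 by limma-voom. PS19 averaged (64): 18 with the suffix term, 137 with a surrogate variable, 141 with the choroid score, 155 with the leading number, 31 without the choroid-rich libraries, 9 with the minimum fold, 173 by DESeq2, 39 by limma-voom. p16KO averaged (37): 20 with the suffix term, 4 with the minimum fold, 104 by DESeq2. The leading number is partly confounded with genotype, since the 4 WT libraries have low numbers and only 1 other library, from PS19, falls in their range, so counts with it as a covariate do not separate the number from genotype.

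Leaving out 1 library at a time gave 124 to 438 calls in PS19 against WT, 0 to 2 in p16KO against WT, 29 to 347 in PS19_p16KO against PS19, 2 to 5 in PS19_p16KO against p16KO, 1 to 160 in the interaction, 15 to 206 in PS19 averaged and 10 to 119 in p16KO averaged. The highest value came without PS19 library 3 in 5 of these. C3ar1 kept a log2 interaction between -2.69 and -2.38 over 28 alternatives, with adjusted p from 4.1e-08 to 0.0545, the last by limma-voom. Replicate numbers do not pair the libraries: those with the same number correlated at a mean r of -0.0159 and 4 of 16 libraries correlated best with their own number. With the replicate block the interaction gave 5 calls and p16KO averaged 23, while the other counts stayed within 1.5 times.

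The share of same-sign genes was 100% over the 3 genes called in PS19_p16KO against p16KO. These were Prnp, Lamr1-ps1 and 4930590L14Rik, which were high in both groups with the transgene, so this share cannot speak for other genes. The opposing Pearson correlation was -0.247, -0.195, -0.214, -0.333, -0.282 and -0.3 in the 6 splits of the PS19 libraries, which removes the shared libraries by construction. Spearman's rho in those splits lay between -0.149 and -0.0176. At this depth 58% of simulated 1.5-fold and 90% of simulated 2-fold changes, in genes with a mean above 1 CPM, were called in PS19_p16KO against PS19.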

Other observations

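In the averaged p16 effect the dentate gyrus list had a median log2 fold change of 0.15 and 11 of 12 positive values, with C1ql2 (0.26), Stxbp6, Prox1 and Npnt higher adjusted over the list alone and 0 over all genes (camera adjusted p = 3.45e-07, adjusted p = 0.154 with an estimated correlation). In the averaged transgene effect ribosomal protein genes had 30 of 30 positive values and a median of 0.11 (adjusted p = 0.321 with an estimated correlation), and border macrophage genes had 0 of 6 positive values and a median of -0.53 (camera adjusted p = 0.000991, adjusted p = 0.208 with an estimated correlation). The border macrophage score was highest in p16KO library 2 (1.447) and WT library 3 (1.378), which were also the highest in the score of fibroblasts and meninges (1.637 and 1.426). Excitatory synapse genes had a median of -0.03 (adjusted p = 0.567 with an estimated correlation).

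Pdcd1, the gene of the immune checkpoint receptor PD-1, was at 0.232 CPM ± 0.164 in WT, 0.133 CPM ± 0.104 in p16KO, 2.14 CPM ± 0.97 in PS19 and 0.115 CPM ± 0.0568 in PS19_p16KO (SD, n = 4). Its log2 fold change in PS19_p16KO against PS19 was -4.13 (edgeR adjusted p = 0.00174).

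The tests below were chosen after the result was seen. Genes that follow the p16 genotype lie close together: the most crowded 20 Mb window, on chromosome 17, held 6 of the 37 called genes, and 16 of 10000 random sets of tested genes reached that number, so random placement is argued against. The share of called genes on chromosome 4, 21.6% against 6.13% of tested genes, had a one-sided Fisher's exact p = 0.00153. Sequence of another strain carried along with the knockout may therefore explain part of this list, such as Klhl9 and Tusc1 near Cdkn2a, rather than loss of p16 itself, although 5 of the 8 start at 140906344 or beyond, far from it, and neither was tested apart from the other. The genes on chromosome 17 and Nnt on chromosome 13, a gene partly deleted in C57BL/6J mice, at 20.2 CPM ± 0.933 in WT and 30.1 CPM ± 2.65 in p16KO, lie on other chromosomes than Cdkn2a, and neighbouring genes can also share regulation, which random sets leave out.

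For the transgene, 7 of 64 called genes lay in 1 window of 20 Mb on chromosome 3, and 76 of 10000 random sets reached that number, which argues against random placement. A candidate explanation is strain sequence around the insertion of the transgene, or an effect of the insertion on its neighbours, and these were not tested. Gbp2b, in that window, was at 0.0402 CPM in WT, 1.09 CPM in p16KO, 2.1 CPM in PS19 and 1.38 CPM in PS19_p16KO. Neither WT nor p16KO carries the transgene, so the insertion does not account for the difference between these 2 groups in this gene.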
